A study of Homo sapiens with 2 samples.

How the data were processed

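Total RNA of HepG2 cells (1 sample) and of HepG2 cells with LRH-1 suppressed by TALENs (1 sample) was labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels' protocols. Groups were taken from the source names in the labels. Nothing in the labels gives further cultures, clones or repeats, so each group has 1 array.

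Spot intensities were made by Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. Per the file headers, the intensity is corrected for background and for spatial trends within an array and comes with an error estimate and with flags for outliers, saturation and signal well above background. No processed value was below 0. The values are not scaled between arrays: its 75th percentile was 134.6 in parental and 132.5 in suppressed cells. The authors also deposited a table of log2 values for 61046 probes. Its columns had a median of 3.91 each, shared their upper quartile and maximum, and had a minimum of 2.32 each, near the log2 of an intensity of 5; that they were quantile-normalized above a floor was read from the values. Against the processed intensities of the same array they correlated with r above 0.999 (0.99996 and 0.99999), so scale and direction are settled and no centring per probe was applied. The genome build named in the array design was not used, since no coordinates or probe sequences are reported here.

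For the main values, log2 of the processed intensity was taken, spots flagged as non-uniform or population outliers on either array were left out (42 transcript probes were lost this way), the spots of a probe were averaged, and each array's 75th percentile over non-control probes was subtracted. The design's 60 negative probes, which the files do not mark as controls, were treated as controls. A probe was called well above background where the flag held for most of its spots. Differences are suppressed minus parental, and an error is either the SD over repeated spots or the scanner's error carried through both arrays; both cover the reading of 1 hybridised sample, not the culture. The 20 reference probes are printed 10 times each and carry RefSeq accessions. All 20 accessions matched a symbol in the RefSeq gene table of GRCh38.p14, used for names only. For the 60904 transcript probes the identifiers were not paired with genes in the sources used here.

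Before the data were examined, the design fixed the scaling, the 2-fold threshold, 27 gene lists, 7 marker lists and the rule for naming genes. That rule put NR5A2 first, then the 10 largest differences in each direction among named protein-coding genes well above background and unsaturated on both arrays with all their probes in 1 direction, then the 5 largest limits each way among genes seen on 1 array only, then 3 long non-coding RNAs each way, then up to 4 list members that differ by 2-fold, or a list's 2 brightest. With 20 named genes this took 15 of them (10 higher, 2 lower, and RPS18, GAPDH and PGK1 as the brightest of their lists). The other 5, among them DYNLL1, RPLP1, RACK1 and GRM4, and the 4 unnamed probes were added after their values were seen. The values of 2 of the named genes are not reported here, though they are part of the counts and list medians. For lists of 5 or more measured genes, the median was set against 10000 random lists, each member drawn from the 200 transcript probes nearest in mean signal.

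The alternatives were median scaling, quantile normalization, the authors' values, dropping saturated spots, other filters on dim probes, other fold thresholds and the brightest probe of a gene. Alternatives added after the data were seen were normexp on the median spot intensity with an offset of 50 (the files have no mean spot intensity, which was planned), keeping flagged spots, counting probes seen on 1 array at their limit, asking for 2-fold beyond the 95% range of the scanner error, and averaging all probes of a gene. Centring on the spike-in probes was not run, because their median intensity (3.07 in parental, 2.24 in suppressed cells) lay at that of the structural negative probes (3.02 and 2.21). No test across genes was run and no p-value was computed, as the design has 1 array per group. List members not on the array by name were left out. Counting was tested on simulated data, in which all 198 probes changed by 4-fold were recovered among 30357 probes and no unchanged probe was counted. This checks the counting only. It does not measure how many of the 2-fold probes on these arrays arise from error. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.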

Results

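Gene expression was measured in HepG2, a human liver cancer cell line, and in HepG2 cells in which LRH-1 had been suppressed with TALENs. LRH-1 is the nuclear receptor encoded by NR5A2, a transcription factor of the liver, and TALENs are engineered nucleases that cut DNA at a chosen sequence. The labels give the genotype of the suppressed cells as LRH-1/-, and how many alleles were altered and whether the cells were a clone or a pool is not given in the sources used here. Each group held 1 one-colour Agilent array, so no difference below has a replicate check and no p-value is given. The number of arrays limits the precision. Both arrays were read in 1 scan, carried 62903 spots each, and had no saturated spot. After outlier-flagged spots were left out, 60882 probes were compared, of which 60862 bore only the array design's own identifiers and 20 bore RefSeq accessions that named a gene. Signals well above background were obtained for 30349 probes (49.8%) in parental cells and for 32949 probes (54.1%) in LRH-1-suppressed cells. The same flag held for 15 of 360 spots of negative probes (4.17%) on the parental array and for 20 of 360 (5.56%) on the suppressed array. Some probes called well above background can therefore be false calls. The transcript of NR5A2 itself was not analysed here, because the identifiers of the transcript probes were not paired with gene names. The labels of the arrays therefore have no check from the targeted gene.

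The first comparison asked how named genes differed between LRH-1-suppressed and parental cells. Of the 20 named genes, 19 were well above background on both arrays, and none differed by 2-fold or more. ODC1, the rate-limiting enzyme of polyamine synthesis, had a signal 1.59-fold higher in the suppressed cells (log2 difference 0.67 ± 0.045, SD over 10 spots). ACTG1, cytoplasmic gamma-actin, was 1.46-fold higher (0.55 ± 0.034, 10 spots). ARHGDIA was 1.44-fold higher (0.52 ± 0.029, 9 spots), as was RPL10, a protein of the large ribosomal subunit (0.52 ± 0.080, 10 spots). The RPL10 probe was dim for a ribosomal protein gene, with signals of 129 in parental and 183 in suppressed cells. In parental cells the probes of RPLP1 and RPS18 read 283168 and 314700. Whether the RPL10 probe reports the main transcript of the gene was not tested. PFN1, the actin-monomer-binding protein profilin, was 1.42-fold higher (0.50 ± 0.010, 6 spots). In the other direction, H3-3A, which encodes the replication-independent histone H3.3, was at 0.667 of its parental level (log2 difference -0.58 ± 0.041, 9 spots).

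COX4I1, a subunit of cytochrome c oxidase, was at 0.838 of its parental level (-0.26 ± 0.049, 10 spots). Smaller positive differences were measured for PRMT1, the main asymmetric arginine methyltransferase (0.32 ± 0.054, 10 spots), EIF3D, a translation initiation factor subunit (0.21 ± 0.051, 10 spots), MTX1, a mitochondrial outer membrane protein (0.20 ± 0.042, 10 spots), and ACTB, beta-actin (0.19 ± 0.037, 9 spots). DYNLL1, a dynein light chain, differed by 0.17 ± 0.061 (10 spots) and turned to -0.017 under quantile normalization and to -0.022 in the authors' values. RPLP1, a ribosomal stalk protein, differed by 0.089 ± 0.053 (10 spots). Under quantile normalization these smaller differences shrank, to 0.13 for PRMT1, 0.044 for EIF3D, 0.081 for MTX1, 0.083 for ACTB and 0.036 for RPLP1, and in the authors' values they were 0.16 for PRMT1, 0.035 for EIF3D, 0.092 for MTX1, 0.18 for ACTB and 0.088 for RPLP1. The smallest differences were those of RPS18, a protein of the small ribosomal subunit (0.064 ± 0.035, 9 spots), the glycolytic enzymes GAPDH (0.062 ± 0.027, 9 spots) and PGK1 (0.053 ± 0.028, 8 spots), and RACK1, a ribosome-associated scaffold (0.049 ± 0.046, 9 spots); RPS18, GAPDH and RACK1 turned negative under quantile normalization (-0.048, -0.029 and -0.0042), and RACK1 also in the authors' values (-0.010), where RPS18 was 0.025 and GAPDH 0.015. With outlier-flagged spots kept, RPS18 was 0.11, and as a mean over their probes, control probes included, GAPDH was 0.18 and PGK1 0.28. GRM4, a metabotropic glutamate receptor, was well above background in 5 of 10 spots on the parental array and in 6 of 10 on the suppressed array, and no fold is given for it.

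The spread between spots covers the reading of 1 hybridised sample only. It was small, with a pooled SD of 0.044 on the log2 scale for the difference between the arrays, and 15 of the 19 genes differed by more than 2 such SDs (13 higher, 2 lower). The scanner software's own error estimate was wider, at a median of 0.21 for a difference over all probes well above background on both arrays. By more than 2 of their own estimates, 7 genes differed, among them ODC1, ACTG1, ARHGDIA, RPL10, PFN1 and H3-3A. Over the 19 genes the estimates were nearly equal, from 0.204 to 0.208, so this came close to 1 common cut. ARHGDIA was no longer beyond 2 of its estimates under quantile normalization (0.38) or in the authors' values (0.39), nor was RPL10 under normexp (0.38), which left 6 genes in each of these settings. Different probes of 1 gene disagreed by more than their spots did. For PGK1, the control probes with 3 and 5 at the end of their names differed by 0.32 ± 0.043 and 0.47 ± 0.040 (SD over 10 spots each), against 0.053 for the accession-named probe. For GAPDH, the corresponding control probes differed by 0.16 ± 0.017 (8 spots) and 0.31 ± 0.040 (10 spots), against 0.062. With the main scaling, the probe ending in 5 lay 0.15 above the probe ending in 3 for both GAPDH (spot SD 0.044) and PGK1 (spot SD 0.059). Under quantile normalization these control probes differed by 0.14 and 0.42 for PGK1 and by 0.029 and 0.12 for GAPDH. In the authors' values they differed by 0.13 and 0.43 for PGK1 and by 0.145 and 0.110 for GAPDH, so for GAPDH the order turned. The cause of this contrast was not tested. The largest gap between probes of 1 gene was 0.42, and the same 7 genes lay beyond it (6 higher, 1 lower) with 75th percentile scaling. This gap lies close to 2 of the scanner estimates, so the match in genes is not separate evidence. Against the gap in each other setting, ARHGDIA dropped out under quantile normalization (gap 0.38) and RPL10 under normexp (gap 0.40). ACTB and ACTG1, and the genes for H3.3, GAPDH and ribosomal proteins, have near-identical relatives or pseudogenes, so their probes can report more than 1 transcript. Bright probes as a whole were shifted upwards, with a median difference of 0.14 for 1931 probes with scaled mean log2 signals above 6. Small positive differences of bright genes among the 13 higher ones are therefore not set apart from that shift.

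**Figure D1:**
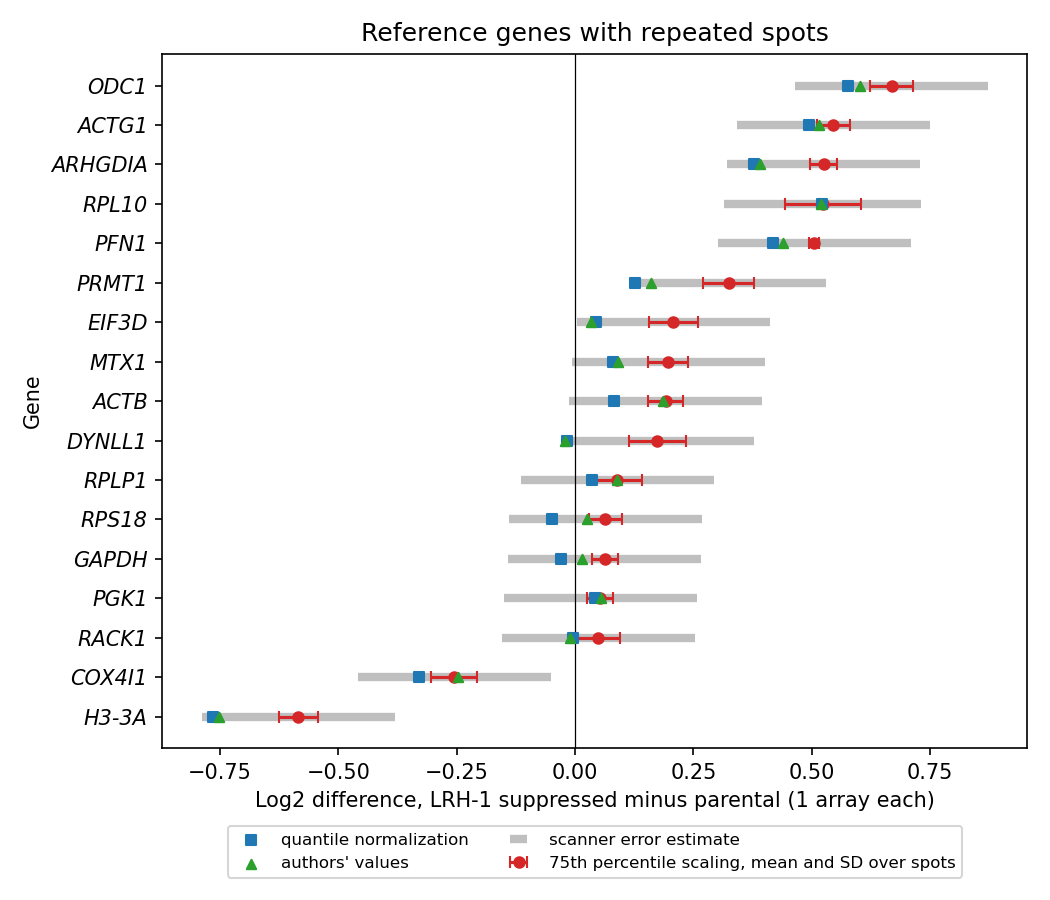
Log2 difference in signal (x axis, LRH-1 suppressed minus parental, 1 array each) for 17 named genes (y axis). Red points and bars are the mean and SD over the repeated spots, grey bars the scanner's error estimate, blue squares quantile-normalized values and green triangles the authors' values; ODC1 sits highest at 0.67, H3-3A lowest at -0.58, and the quantile-normalized GAPDH, RPS18, RACK1 and DYNLL1 and the authors' RACK1 and DYNLL1 lie below 0.

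Each named gene was also set against transcript probes of similar brightness. For ODC1, 32% of the 200 transcript probes closest in mean signal differed at least as far from 0. For ACTG1 and PFN1 the shares were 11% and 14%, and for ARHGDIA and RPL10 they were 36.5% and 43.5%. For H3-3A the share was 20.5%. These shares count probes in both directions. Taking the direction into account, 3.5% of the probes matched to H3-3A had a lower difference than it. For ACTG1 and PFN1, 91% and 90.5% of the matched probes had a lower difference. The median difference of the 19 genes was 0.19, at the 87.2th percentile of 10000 random lists matched on mean expression, whose medians ranged from -0.13 to 0.29 (central 95%). These percentiles describe this pair of arrays.

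Of the 27 gene lists fixed before the data were examined, 2 had a measured member by name. The housekeeping list had 5 of its 18 members measured, among them ACTB, RPS18, GAPDH and PGK1. The median difference of the 5 was 0.064, at the 51.5th percentile of 10000 matched random lists (central 95% from -0.25 to 0.49). In the glycolysis list 2 of 22 members were measured, GAPDH and PGK1, with a median of 0.058 and too few members for a percentile; it was 0.0060 under quantile normalization, 0.035 in the authors' values and 0.19 with the brightest probe of each gene. With the brightest probe the housekeeping median was 0.16, and with outlier-flagged spots kept it was 0.11. The other 25 lists, among them LRH-1 target genes, bile acid synthesis, cholesterol and fatty acid metabolism, hepatocyte proteins and transcription factors, cell cycle and inflammation, were not analysed here for want of gene names. The same holds for the 7 lists of markers of other cell types, so the purity of either culture was not assessed.

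The second comparison asked how widely the probes differed. Among the 28760 probes well above background on both arrays, 3357 (11.7%) were at least 2-fold higher in LRH-1-suppressed cells and 2918 (10.1%) at least 2-fold lower, while 22485 (78.2%) lay within 2-fold. Across these probes, which are not independent replicates, the log2 signals of the arrays correlated with Pearson's coefficient of 0.933 and Spearman's of 0.911. The quartiles of the differences were -0.36 and 0.49, with a median of 0.064. Among large differences the lower side held more probes: 487 probes were at least 8-fold lower in suppressed cells and 195 at least 8-fold higher. Under normexp these counts were 267 and 71. The lowest probes measured on both arrays, ASHGV40054173 and ASHGV40037863, had signals of 10936 and 8318 in parental cells and of 16.7 and 13.1 in suppressed cells, log2 differences of -9.33 ± 0.28 and -9.29 ± 0.32 (scanner error). Their dim signals lay near 10.7, the lowest signal called well above background on the suppressed array. The signal of 13.1 was under that level on the parental array (14.4). The highest measured on both arrays, ASHGV40049021 and ASHGV40012467, had signals of 19.8 and 61.8 in parental cells and of 1256 and 3785 in suppressed cells, differences of 6.01 ± 0.30 and 5.96 ± 0.22. These 4 probes were chosen after their values were seen, and coding and non-coding transcripts were not set apart.

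**Figure D2:**
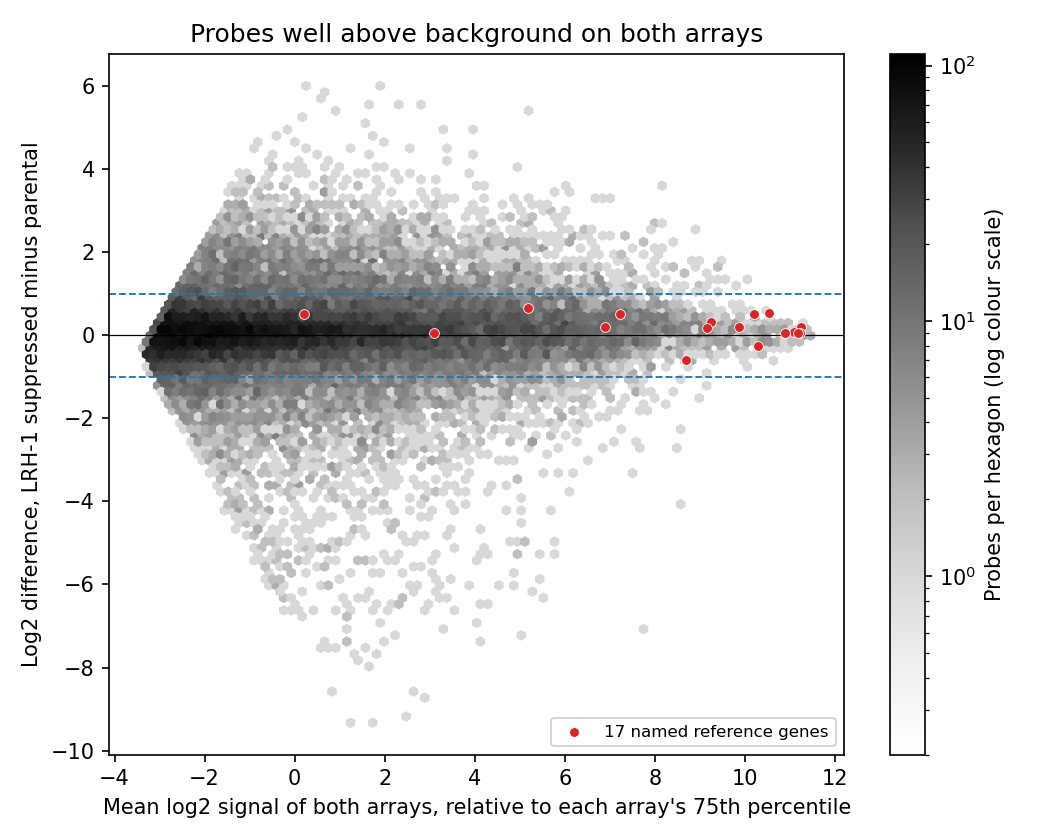
Log2 difference (y axis, LRH-1 suppressed minus parental) against mean log2 signal relative to each array's 75th percentile (x axis) for 28760 probes well above background on both arrays, shaded by number of probes, with 17 named genes in red. Dashed lines mark 2-fold; 3357 probes lie on or above the upper line, 2918 on or below the lower line, and the lower tail reaches -9.33.

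Further probes were well above background on 1 array only, 4189 in LRH-1-suppressed cells and 1589 in parental cells, and for these the difference has only a lower limit. It was taken as the bright signal over the higher of the dim array's lowest well-above-background signal and the probe's own. On that limit, 646 probes were at least 2-fold higher in suppressed cells and 986 at least 2-fold higher in parental cells, and at the 8-fold level the numbers were 58 and 273. These numbers are not on equal terms. The lowest signal called well above background was 14.4 on the parental and 10.7 on the suppressed array. That lowers the limits of probes seen in suppressed cells only, and how much of the gap it makes was not tested. The largest limits were at least 303-fold higher in suppressed cells, from signals of 2.96 in parental and 4302 in suppressed cells, and at least 437-fold lower, from signals of 4754 and 7.49. For 1615 of the probes seen in suppressed cells only the limit was under 1, and they have no fold, against 0 of those seen in parental cells only. Neither array showed a signal well above background for 26344 probes, and a difference in those was not detectable.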

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

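In this part the counts at a common level with no margin, and those with the margin alone, were chosen after the other results were seen, and the test with both was brought into line with its wording after a first run with a stricter margin. Apart from those for GAPDH and PGK1, control probes are not part of the comparisons above, and 4 of the 94 control and negative probes with at least 6 spots were well above background in most spots on the LRH-1-suppressed array and not on the parental array, against 0 the other way. ERCC-00097_63 was well above background in 100% of 35 spots on the suppressed array and in 0% on the parental array, with signals of 16.9 and 4.62. For ERCC-00077_121 the shares were 100% and 40% (signals 18.2 and 13.8), for (+)E1A_r60_a22 71.4% and 8.57% (12.3 and 10.5), and for ETG09_35454 91.7% of 12 spots and 50% (16.5 and 17.4).

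Transcript probes followed the same direction: 4189 were well above background on the suppressed array only and 1589 on the parental array only, a ratio of 2.64. The negative controls scattered less on the suppressed array (SD 1.70) than on the parental array (SD 2.00), and its lowest signal called well above background was 10.7 against 14.4. When 1 common level was asked of both arrays, with the dim side also at least 2-fold under the bright side, 1436 probes were above it on the suppressed array only and 1722 on the parental array only, a ratio of 0.834. The common level alone, with no 2-fold margin, gave 2390 and 2439 (0.980), while the 2-fold margin alone, on probes as called by the scanner software, gave 1907 and 1419 (1.34). Lower background noise on the suppressed array may account for the excess among transcript probes, though the margin also lowered it. The signals of ERCC-00097_63 and ERCC-00077_121 lay above 14.4 on the suppressed array and under it on the parental array, so a lower level for calling a signal does not by itself account for those 2 control probes, and their cause was not tested. A biological gain of transcripts weaker than the common level was not tested.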

How the results depend on the processing

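The normexp, outlier-spot, limit, scanner-error and all-probe settings were chosen after the data were seen. The counts of 2-fold probes (3357 higher, 2918 lower) stayed within 1.5 times under median scaling, quantile normalization, the authors' values and with outlier-flagged spots kept, and the share of higher probes among them stayed between 50.6% and 54.8% under the settings other than the scanner-error one. They moved to 2192 and 1865 under normexp. Its offset of 50 exceeds the median processed intensity of either array (15.0 in parental, 14.6 in suppressed cells). Such an offset draws the ratios of dim probes towards 1 by construction, and how much of the move it made was not tested. The counts also moved to 6639 and 6350 with no filter on dim probes. They moved to 6086 and 5013 at 1.5-fold and to 1671 and 1555 at 3-fold. At 2-fold beyond the 95% range of the scanner error they moved to 1974 and 1784. With probes well above background on at least 1 array, the higher count moved to 5264 while the lower, at 4337, stayed within 1.5 times; this count and the unfiltered one take signals not well above background at face value, and with probes seen on 1 array at their limit the counts were 4003 and 3904, both within 1.5 times. The housekeeping median (0.064) lay between 0.041 and 0.16 and the glycolysis median (0.058) between 0.0060 and 0.19 over the settings run on them, above 0 in each. Among named genes, quantile normalization reversed GAPDH (-0.029), RACK1 (-0.0042), RPS18 (-0.048) and DYNLL1 (-0.017). The authors' values reversed RACK1 (-0.010) and DYNLL1 (-0.022). With the main scaling, the median difference over probes well above background on both arrays rose with brightness. It was -0.038 for 5124 probes with scaled mean log2 signals under -2 and 0.14 for 1931 probes above 6. All the genes that reversed lay above 6. Whether this trend made the reversals was not tested. The brightest of its 3 probes gave PGK1 0.32, and the mean over 3 probes gave GAPDH 0.18 and PGK1 0.28. Dropping saturated spots moved nothing, since there were none, and spike-in centring and normexp on mean spot intensities were not run. No paired analysis was possible because each group holds 1 array, and leaving out an array leaves no comparison. Signal over background limits the 26344 probes seen on neither array.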

Other observations

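Of the tests in this part, the one on probes next in number to strongly lower probes and both on windows of probe numbers were chosen after related results were seen; after its test had been run, the explanation by a local artefact was also narrowed from one that included faulty spots in general, and patterns in neighbouring numbers and in windows were joined into 1. Probes close in the array design's own numbering differed alike between LRH-1-suppressed and parental cells. Over 15721 pairs of consecutive numbers, both well above background on both arrays, the log2 differences correlated with r = 0.166 across probes, against 0.012 as the upper end of the central 95% of 1000 shuffles, and 73.1% of the 968 pairs in which both probes differed by 2-fold went the same way. Neighbouring positions on the slide do not account for this. Of the 15721 pairs, 15342 already lay more than 20 rows or columns apart, and these gave the same 0.166, while spots side by side gave 0.0077. Nor does brightness account for it, as the correlation was 0.166 after its trend was removed. The pattern also reached over long stretches: medians of 122 windows of 500 numbers had an SD of 0.097, which was 1.66 times the upper end of the central 95% of 1000 shuffles that kept stretches of 20 numbers whole, so several probes of 1 transcript are not the whole of it, and 1.74 times after each spot's local median on the slide was taken off. Between single numbers the correlation fell from 0.166 at a step of 1 to 0.11 at a step of 2, 0.082 at 3 and 0.051 at 5. It was 0.026 at a step of 10, 0.034 at a step of 20 and 0.018 at a step of 200. Most of the correlation of consecutive numbers thus lay within short stretches, where several probes of 1 transcript were not set apart. The highest and lowest medians were in the window of last digits 27501 to 28000, with a median of 0.34 and 24.0% of 221 probes at least 2-fold higher, and that of 15001 to 15500, with -0.18 and 16.6% of 247 probes at least 2-fold lower. A candidate explanation for the shifts over long stretches is that the numbering follows genome position or transcript class. Whole regions or classes would then have shifted, as a difference in copy number between the cell lines could do. This was not tested without a map of the probes, and LRH-1 suppression itself stays open as well.

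Among probes well above background on both arrays, 487 were at least 8-fold lower and 195 at least 8-fold higher in LRH-1-suppressed cells, although more probes were 2-fold higher (3357) than 2-fold lower (2918). The ratio of lower to higher probes was at least 2.40 under median scaling, quantile normalization and the authors' values. These settings moved the median difference only from 0.064 to between 0.044 and 0.077. They could therefore not show whether a larger error in the scaling between the arrays plays a part. Under normexp the counts were 267 and 71. A local artefact on the slide is argued against: 4.72% of the strongly lower probes had an adjacent spot that was strongly lower too, 0.786 times the share in 1000 random placements. Scattered faulty spots as the whole cause are argued against by probes next in number to strongly lower ones, of which 28.0% were at least 2-fold lower, 2.76 times the share of all probes. The lowest signal called well above background was 10.7 on the suppressed and 14.4 on the parental array. This can let more lower than higher probes into the count, and its share was not tested. With probes well above background on at least 1 array, taken at face value, the counts were 1139 lower and 470 higher. LRH-1 suppression, selection of a clone after TALEN treatment and a difference between cultures are each possible and cannot be separated with 1 array per group.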
